A study of Arabidopsis thaliana with 9 samples.

How the data were processed

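Small RNA was measured in 3 wild-type (Col-0) and 3 dxo1-2 libraries of Arabidopsis thaliana, and total RNA with ribosomal RNA removed in 3 dxo1-2 libraries by stranded RNA-seq. The plants were 21 days old and grew on soil in 16 h of light and 8 h of dark after 2 days of stratification at 4 °C. The labels describe the replicates as biological. Libraries were grouped by their genotype and assay labels, and the replicate numbers were taken from the titles. Wild-type RNA-seq libraries, which the series' design text places in another submission, were not analysed here.

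The values were raw counts per gene as the authors deposited them, 1 table per library, with 37184 genes and 5 summary lines each. Per the submitters' processing notes, HISAT2, HTSeq, DESeq2, Bowtie and bedtools were used with the genome build TAIR10. The role, version and settings of each tool were not given in the sources used here, including the strand setting and the rule for reads with several matches. Counts of a gene and of an overlapping or antisense gene can therefore not be told apart with certainty. In the small RNA tables the summary line for reads with several matches held 0, while copies of 1 tRNA carried nearly equal counts. Of 6046 genes with a mean of at least 50 counts, 155 matched another gene within 1% (or 1 count) in all 6 libraries, and 67 of these were tRNA genes. Such genes are treated as sharing reads. The summary lines stayed out of tests, and out of library sizes except in the alternative with all lines as library size. Reads without an annotated feature made up 67.6% ± 1.20 (SD, n = 3) of all lines in Col-0 small RNA libraries and 62.6% ± 0.816 in dxo1-2, and reads on genes 22.7% ± 0.830 and 27.0% ± 0.554. Ambiguous reads made up 1.97% ± 0.572 and 1.53% ± 0.324. In the RNA-seq libraries 78.3% ± 0.835 of all lines were on genes, 8.55% ± 0.766 had no feature and 10.5% had several matches.

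Gene symbols, classes and neighbours were taken from a RefSeq gene table of the assembly TAIR10.1, which matched 36899 identifiers. The pseudogene class follows that table, and transposable element genes were given no class of their own. The 285 unmatched identifiers were plastid and mitochondrial genes, recognised by their prefix. No coordinates are given, because the table's assembly differs by name from the build of the counts. MicroRNA and trans-acting siRNA loci were not analysed here, and the gene counts, class counts and shares given include none of them.

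Gene counts per library ranged from 3976221 to 4393015 in Col-0 small RNA, from 5022945 to 5698185 in dxo1-2 small RNA and from 60138933 to 71210737 in RNA-seq. Small RNA counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM scaling, the default expression filter, genotype as the only term, two-sided p-values and Benjamini-Hochberg adjustment at 0.05. The filter kept 11534 genes. Log2 fold changes are dxo1-2 over Col-0 with a prior count of 0.125. The ± after a log2 fold change is an approximate standard error (SE), the absolute log2 fold change over the square root of the test's F. It can fall below counting error where a group held few counts. Scaled counts (CPM, counts per 1e6 counts) were computed from the deposited counts with TMM scaling and are given as mean ± SD. Where a group held no count, the fold was computed against 3 counts per library, and where it held 1 to 3 counts a ratio of depth-scaled summed counts is given with an exact binomial 95% interval, which covers counting error only.

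Gene lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 9 lists. Shares of counts per gene class were compared by an exact two-sided permutation test over the 10 splits of 3 against 3 libraries, adjusted over the classes. RNA-seq levels were described without a test, since these libraries were of 1 genotype. The edgeR test was tested on simulated data for the small RNA comparison, with 11534 genes of which 200 were changed. It recovered 67% of 100 genes changed by a log2 of 1 and 89% of 100 genes changed by a log2 of 2, and called 0.0441% of 11334 unchanged genes. The simulated changes were few and balanced in direction, so the simulation did not test the scaling.

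The design, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named DXO1, the 6 genes with the largest fitted rise and the 6 with the largest fitted fall among those past the threshold with a mean of at least 50 counts and no overlap between groups, and the 2 members with the smallest adjusted p of each list with at least 3 tested members. For RNA-seq it named the 6 genes with the highest mean CPM and the highest member of each list. GAE6, HBI1, MYB28, NIA1, NIA2, AGO3, AT4G37175, AT1G73650 and other list members named to spell out a small count were chosen after their values were seen. Alternatives covered scaling, the low-count filter, DESeq2 1.42.0, limma-voom, a fold threshold, a replicate block, single libraries left out, and the correlation and background of the list tests.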

Results

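The series compared small RNA in Col-0 and dxo1-2 seedlings and added RNA-seq of dxo1-2. DXO1 belongs to the DXO family of enzymes that act on RNA 5′ ends, and the series' title ties it to RNA turnover and the chloroplast. There were 3 Col-0 small RNA libraries with 3976221, 4140212 and 4393015 counts on genes, 3 dxo1-2 small RNA libraries with 5698185, 5137378 and 5022945, and 3 dxo1-2 RNA-seq libraries with 71210737, 60138933 and 64478196. Small RNA libraries of 1 genotype were close to each other. Correlations of log CPM across genes were 0.971 to 0.976 within Col-0, 0.986 to 0.987 within dxo1-2 and 0.880 to 0.902 between genotypes.

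DXO1 (AT4G17620) itself carried few small RNA counts, 8.31 ± 3.27 CPM in Col-0 and 9.26 ± 0.744 CPM in dxo1-2 (SD, n = 3 each). The difference did not pass the test, with a log2 fold change of 0.15 ± 0.28 and an adjusted p of 0.667 in edgeR. In the dxo1-2 RNA-seq libraries DXO1 stood at 1.51 ± 0.222 CPM (n = 3), from 108, 76 and 113 counts. With all lines of the table as the library size, an alternative chosen after the data were seen, the small RNA log2 fold change was 0.73 (adjusted p = 0.0350). Without a wild-type RNA-seq level these values check nothing about the genotype label.

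Small RNA counts over many transcribed genes were far higher in dxo1-2 than in Col-0. GAE6 (AT3G23820), a UDP-glucuronate epimerase of pectin synthesis, rose from 76.2 ± 12.4 to 5276 ± 339 CPM (n = 3 each). The transcription factor gene bZIP2 (AT2G18160) rose from 13.4 ± 5.88 to 4097 ± 119 CPM, and EXO (AT4G08950) from 6.08 ± 5.12 to 3332 ± 682 CPM. HBI1 (AT2G18300), a bHLH transcription factor of growth, and MYB28 (AT5G61420), a regulator of aliphatic glucosinolate synthesis, rose with log2 fold changes of 6.55 ± 0.20 and 5.77 ± 0.14. A smaller number of loci lost nearly all their small RNA counts, among them the pseudogene AT3G22955 and the Deg-type protease gene DEG6 (AT1G51150).

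In edgeR, 3093 genes were higher and 2651 lower in dxo1-2 among 11534 tested, and 6466 genes had an unadjusted p under 0.05. The adjusted p was 2.0e-11 for GAE6, 3.5e-11 for bZIP2 and MYB28, 6.8e-10 for EXO and 3.7e-10 for HBI1. The non-coding RNA gene AT1G06147 had 0 counts in every Col-0 library and 749, 617 and 648 in dxo1-2. Against 3 counts per library it was at least 140-fold higher. AT5G42680 had 1 count in Col-0 and 364 in dxo1-2, a ratio of 228 (95% interval 40.7 to 9041). PH1 (AT2G29700) had 3 and 495, a ratio of 103 (35.2 to 504). AT3G23870, which overlaps another gene, rose with a log2 fold change of 6.76 ± 0.24.

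Among the falls, AT3G22955 went from 249 ± 55.8 to 0.298 ± 0.390 CPM, a log2 fold change of -9.64 ± 0.32. DEG6 had 1732 counts in Col-0 and 3 in dxo1-2, a ratio of 921 (314 to 4468). The pseudogene AT2G32291 fell from 129 ± 32.2 to 1.57 ± 0.563 CPM. AT2G34060, the glutaredoxin gene GRX480 (AT1G28480) and the beta-glucosidase gene DIN2 (AT3G60140) fell with log2 fold changes of -4.35 ± 0.50, -3.76 ± 0.25 and -3.40 ± 0.17 (adjusted p = 2.6e-05, 1.9e-07 and 1.3e-08).

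The balance of higher and lower calls rested on the scaling. The median log2 fold change of all tested genes was -0.019 with TMM, and 53.8% of calls were higher. It was 0.32 with library totals alone (4703 higher, 809 lower), 0.11 with TMM from pseudogenes (3668 and 1753), -0.50 with TMM from small nuclear RNA genes (2065 and 5373) and 0.55 with all lines of the table as the library size (6828 and 502).

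**Figure D1:**
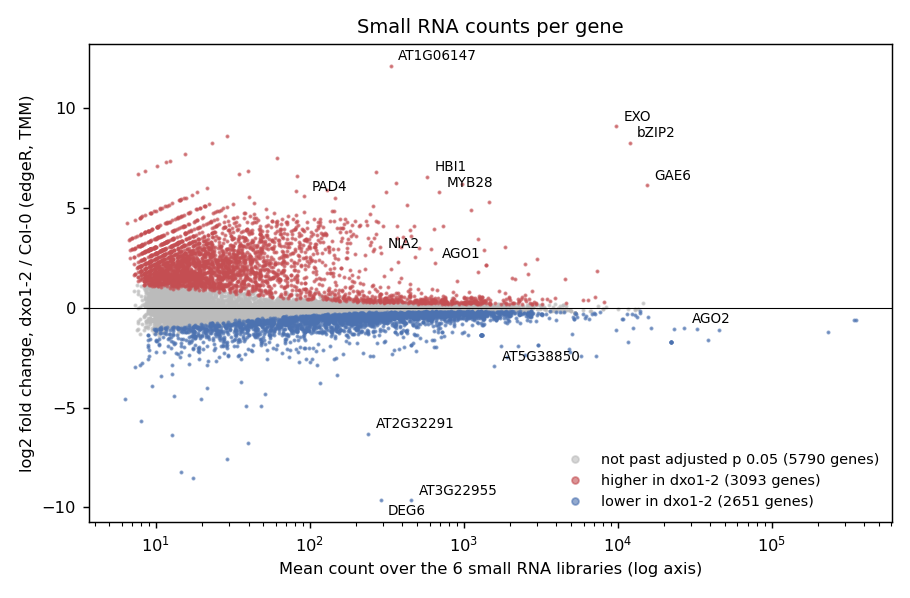
Each point is 1 of the 11534 tested genes, with its mean count over the 6 small RNA libraries on a log axis and its log2 fold change between dxo1-2 and Col-0 from edgeR with TMM, where fitted folds of genes with 0 counts in a group depend on the prior count. The 3093 higher genes reach far above 0 at low and high counts, while most of the 2651 lower genes lie close below 0, and with all lines as library size the split was 6828 higher to 502 lower.

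**Figure D2:**
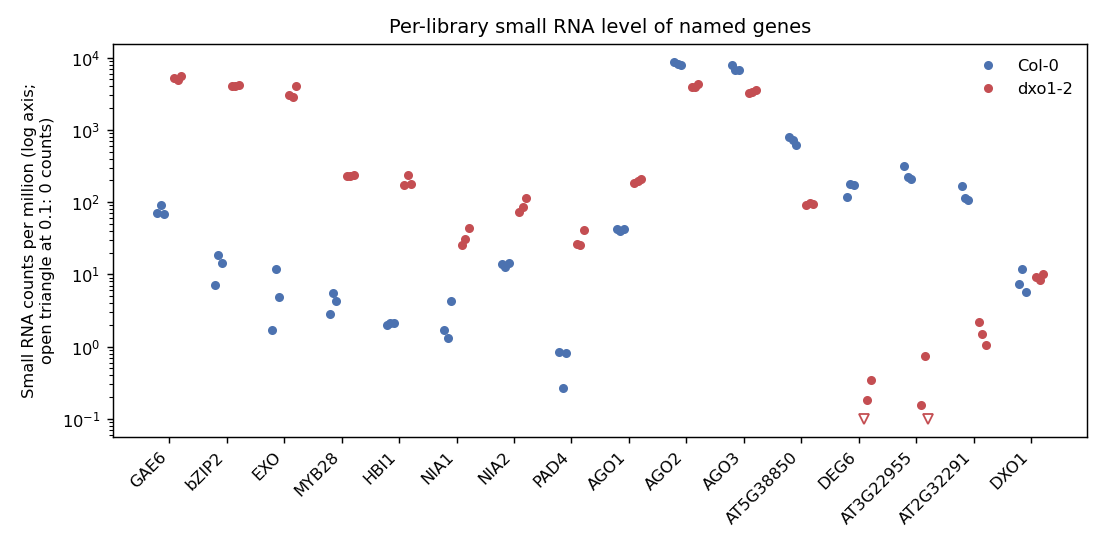
Small RNA CPM on a log axis for named genes in each of the 3 Col-0 and 3 dxo1-2 libraries, with open triangles for libraries with 0 counts. GAE6, bZIP2 and EXO stand above 2000 CPM in dxo1-2 and below 100 CPM in Col-0, while the 6 libraries overlap at DXO1.

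By gene class, protein-coding genes had 2642 higher and 1119 lower calls among 6530 tested, against 2021 and 2040 with TMM from small nuclear RNA genes, 3891 and 300 with all lines, and 554 and 585 among genes with a mean of at least 50 counts. Of 339 tRNA genes 1 rose and 108 fell, with a median log2 fold change of -0.39, which turned to 0.18 with all lines as library size (34 higher, 48 lower). The counts were 16 and 56 with library totals alone and 14 and 102 without Col-0 replicate 3. AT4G37175, a tRNA gene, had 8155 ± 1231 CPM in Col-0 and 2459 ± 271 in dxo1-2, and AT1G73650, which overlaps another gene, had nearly equal counts, so these cannot be counted as separate changes. Other copies of tRNA genes can share reads too, so the 108 falls need not be separate changes. Small nuclear RNA genes went the other way, with 12 of 25 higher and 0 lower. With library totals alone 21 of them were higher, with all lines 24, and with TMM from these genes themselves 1. All 3 tested rRNA genes fell, with a median of -0.64, which was -0.31 with library totals alone and -0.071 with all lines, where 1 was lower in each case, as without dxo1-2 replicate 3. The rRNA genes AT3G41768 and AT2G01010 had close totals over the small RNA libraries, 2117436 and 2062748 counts. They can share reads, so their falls need not be separate.

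Transposable element genes had no class of their own here and may be among the pseudogenes. Pseudogenes had 388 higher and 1232 lower calls among 4081 tested and a median of -0.14. The balance turned to 1341 higher and 170 lower with library totals alone (median 0.20) and to 2727 and 93 with all lines (median 0.44). With TMM from small nuclear RNA genes 25 pseudogenes were higher and 2730 lower. Their share of gene counts was nevertheless higher, 44.0% ± 3.33 in Col-0 and 50.4% ± 2.59 in dxo1-2 (n = 3 each), and among genes with a mean of at least 50 counts 826 pseudogenes were higher and 556 lower. Long and other non-coding RNA genes had 37 higher and 169 lower calls among 386, with a median of -0.49 that turned to 0.083 with all lines (92 higher, 56 lower). The counts were 63 and 85 with library totals alone and 13 and 268 with TMM from small nuclear RNA genes. Small nucleolar RNA genes had 13 higher and 20 lower calls among 170.

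As shares of gene counts, protein-coding genes took 22.4% ± 1.02 in Col-0 and 25.4% ± 1.24 in dxo1-2, tRNA genes 6.73% ± 0.503 and 4.08% ± 0.392, and long and other non-coding RNA genes 3.32% ± 0.269 and 2.70% ± 0.151. As a share of nuclear counts without rRNA and tRNA genes, the difference was 0.144 percentage points for protein-coding genes (2.98 as reported) and 1.05 for pseudogenes (6.40 as reported). Genes were removed by class alone, so AT1G73650, with nearly the counts of a tRNA gene, stayed among protein-coding genes. It had 89627 summed counts in Col-0 and 42909 in dxo1-2, which lowers the protein-coding difference. Small nuclear RNA genes took 0.135% ± 0.00815 and 0.247% ± 0.0461. In these classes and in pseudogenes the groups did not overlap, and the exact permutation p was 0.1 (adjusted 0.14), the smallest that 3 against 3 libraries allow. The rRNA share, 23.1% ± 4.90 and 16.9% ± 3.44, and the small nucleolar share, 0.298% ± 0.0444 and 0.351% ± 0.0230, overlapped between genotypes (exact p = 0.3 and 0.2). Plastid and mitochondrial genes were listed at 0 in all 6 small RNA libraries. Whether reads of these genomes were counted is not given in the sources used here, so the shares hold for nuclear genes.

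**Figure D3:**
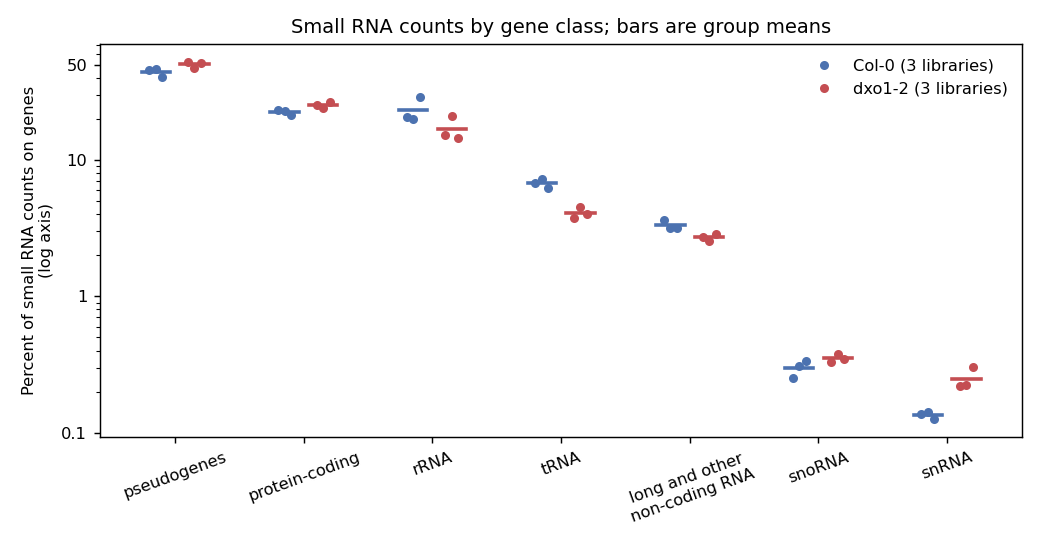
Percent of gene counts taken by each gene class in each small RNA library, on a log axis, with bars at the means of 3 libraries per genotype. The tRNA share is lower and the small nuclear RNA share higher in all 3 dxo1-2 libraries, while rRNA shares overlap.

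Most tested genes of salicylic acid defence rose. Of 20 members 11 were tested, and the others had too few counts. The filter can admit a member through its dxo1-2 counts alone. Of the 11 tested members, 10 were higher and 0 lower, and 10 were higher when adjusted over the list alone. The lipase-like regulator PAD4 (AT3G52430) rose from 0.639 ± 0.324 to 31.2 ± 8.66 CPM (log2 fold change 5.56 ± 0.37, adjusted p = 2.1e-07) and WRKY70 (AT3G56400) with a log2 fold change of 2.85 ± 0.33. NPR1 (AT1G64280), a salicylic acid receptor gene, did not pass, at a log2 fold change of 0.72 ± 0.56. The list's median log2 fold change was 2.71, its camera adjusted p was 0.00104, and the call was lost at an adjusted p = 0.478 with an estimated correlation. Among protein-coding genes with an RNA-seq level of at least 1 CPM, a background chosen after the data were seen, camera gave an adjusted p of 0.132.

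The pentatricopeptide repeat (PPR) loci known to give secondary siRNAs had 13 of 17 members lower and 0 higher, and 13 lower adjusted over the list alone, with a median of -0.31 that turned to 0.027 with library totals alone and 0.27 with all lines, where 12 were higher. AT1G62860 fell by 1.14 on the log2 scale (SE 0.092, adjusted p = 1.1e-06) and AT1G12775, which overlaps another gene, from 248 ± 12.4 to 141 ± 13.9 CPM. The camera adjusted p was 0.00255, and 0.478 with an estimated correlation. Without dxo1-2 replicate 1 only 6 members were lower. These loci are near copies of each other and can share reads.

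Argonaute genes went both ways. AGO1 (AT1G48410), the main effector of microRNAs, rose from 41.7 ± 1.83 to 195 ± 11.2 CPM, while AGO2 (AT1G31280) fell from 8268 ± 435 to 4064 ± 211 CPM and AGO3 (AT1G31290) from 7144 ± 657 to 3400 ± 150 CPM. AGO3 and AGO2 are related copies whose counts stood in a ratio of 0.829 to 0.902 in every library, so shared reads stay possible. In the list of small RNA machinery 1 of 6 tested members rose and 3 fell, the third being DCL4 (log2 fold change -0.89 ± 0.31), with the same counts adjusted over the list alone. Its median was -0.31, its mean 0.073 and the direction of camera down (adjusted p = 0.948), and the median turned to 0.023 with library totals alone and 0.26 with all lines.

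The other targets of microRNAs or trans-acting siRNAs had 4 higher and 5 lower members of 18, also adjusted over the list alone. AGO1, GRH1, HAM3 and PHB rose, and AGO2, AFB2, BHLH77, HAM2 and HAM1 fell. The median was 0.21 and the mean 0.17, while camera pointed down (adjusted p = 0.948). With library totals alone 6 were higher and 2 lower, with all lines 9 and 1, and with TMM from small nuclear RNA genes 2 and 8 (median -0.28).

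Among resistance genes of the NLR type, AT5G38850 fell from 712 ± 82.2 to 93.6 ± 2.83 CPM (log2 fold change -2.93 ± 0.092, adjusted p = 3.7e-10) and AT5G43740, which overlaps another gene, by 0.61 on the log2 scale, a call lost with library totals alone (adjusted p = 0.0641). In all 5 of 14 members fell and 2 rose, AT5G41740 and RPP1, with the same counts adjusted over the list alone. The camera adjusted p was 0.0595, and the median of -0.21 turned to 0.13 with library totals alone (3 higher, 1 lower) and 0.36 with all lines (8 and 1). It was -0.12 without dxo1-2 replicate 2. The lower members numbered 3 without Col-0 replicate 1, Col-0 replicate 2 or dxo1-2 replicate 3, and without the last 1 member was higher.

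Nuclear photosynthesis genes had 17 higher and 2 lower members of 48, also adjusted over the list alone. The plastocyanin gene PETE1 (AT1G76100) rose from 3.45 ± 0.830 to 24.9 ± 3.52 CPM and the light-harvesting gene CAB2 (AT1G29920), whose copies can share reads, from 168 ± 80.4 to 915 ± 112 CPM. PSBO2 and PSAL fell, while 27 members were higher and 1 lower with library totals alone, 30 and 0 with all lines, and 9 and 18 with TMM from small nuclear RNA genes (median -0.23). The list's median was 0.26 and its camera adjusted p 0.0948, and the median was 0.024 without Col-0 replicate 2, 0.095 without Col-0 replicate 1, 0.15 without dxo1-2 replicate 2 and 0.56 without Col-0 replicate 3. Without Col-0 replicate 3 the higher members numbered 27, and the lower ones numbered 5 without Col-0 replicate 1, 7 without Col-0 replicate 2, 1 without dxo1-2 replicate 1 and 0 without dxo1-2 replicate 3.

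Of 14 chlorophyll synthesis genes 5 rose, also adjusted over the list alone, and 0 fell. CHLM (AT4G25080), which overlaps another gene, rose from 3.52 ± 2.18 to 15.3 ± 2.70 CPM. GUN4 (AT3G59400), also overlapping another gene, had 2 counts in Col-0 and 45 in dxo1-2, a ratio of 14.1 (3.69 to 120). HEMA1, CRD1 and CH1 were the others. The median was 0.30 and the camera adjusted p 0.690, and with TMM from small nuclear RNA genes 4 were higher and 4 lower (median -0.19). The count of higher members was 3 without Col-0 replicate 1, Col-0 replicate 2 or dxo1-2 replicate 2, and without Col-0 replicate 2 another 3 were lower. The median was -0.0089 without Col-0 replicate 1, 0.67 without Col-0 replicate 3, 0.20 without Col-0 replicate 2 and 0.19 without dxo1-2 replicate 3.

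The nitrate reductase genes NIA1 (AT1G77760) and NIA2 (AT1G37130) rose from 2.44 ± 1.63 to 33.4 ± 9.15 CPM and from 13.7 ± 0.819 to 91.0 ± 21.6 CPM. They were the 2 tested members of 4 loci known to give siRNAs when RNA quality control fails, and both also passed adjusted over the list alone, too few for a list test. Of 9 RNA decay genes 0 rose and 1 fell, and 0 passed adjusted over the list alone. The one that fell was the exosome nuclease gene EMB2763 (AT2G17510), which overlaps another gene and had a log2 fold change of -0.37 ± 0.14 (adjusted p = 0.0494) that turned to 0.21 with all lines as library size. The call was also lost without Col-0 replicate 1 or 3 or any 1 of the dxo1-2 replicates, at adjusted p values from 0.0537 to 0.171. It was lost too with RLE scaling (0.0584), limma-voom (0.0615), DESeq2 (0.0696), library totals alone (0.919) and TMM from pseudogenes (0.197). The same held for both other count filters, the fold threshold and thinned counts. It was kept without rRNA and tRNA genes, without Col-0 replicate 2, with the replicate block and with TMM from small nuclear RNA genes. The exonuclease gene XRN4 (AT1G54490) had a log2 fold change of 0.78 ± 0.36 (adjusted p = 0.0868), which passed without Col-0 replicate 2 (0.0175), with library totals alone (0.0122) and with all lines (0.00419). The list's median was 0.15 and mean 0.22 while camera pointed down (adjusted p = 0.996). With library totals alone 2 members of this list were higher and 0 lower, and with all lines 5 and 0. The counts were 1 and 1 without Col-0 replicate 2, and 1 and 0 without Col-0 replicate 3.

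Of 5 housekeeping genes 1 rose, ACT2 (AT3G18780), from 10.7 ± 2.69 to 19.8 ± 2.59 CPM, also adjusted over the list alone, a call lost with TMM from small nuclear RNA genes (adjusted p = 0.193). EF1B (AT5G19510), which overlaps another gene, had a log2 fold change of 0.96 ± 0.50 (adjusted p = 0.132) and passed without Col-0 replicate 3 (0.0187), with library totals alone (0.0267) and with all lines (0.0144). The list's median was 0.072 and its camera adjusted p 0.948, and the median lay below 0 without Col-0 replicate 1, Col-0 replicate 2 or dxo1-2 replicate 2. Of 16 nuclear genes for plastid transcription 2 were tested and PTAC2 rose (log2 fold change 1.33 ± 0.49), also adjusted over the list alone. Flower and root markers were too low to be tested, with 14 and 4 summed counts in Col-0 and 16 and 18 in dxo1-2. The 1 tested senescence marker, SEN1, had a log2 fold change of -0.57 and did not pass over all genes (edgeR, adjusted p = 0.0753). With 1 tested member, adjustment over the list alone leaves the unadjusted p, which was under 0.05.

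**Figure D4:**
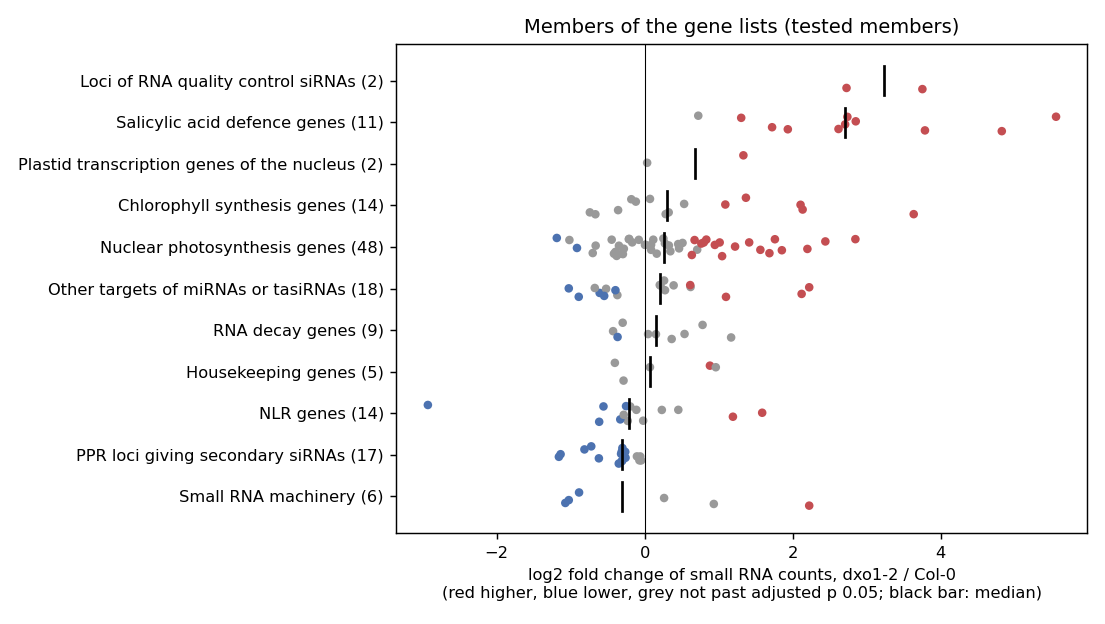
Log2 fold change of small RNA counts for each tested member of the gene lists, with a black bar at each list's median and colours for the call at an adjusted p of 0.05. Salicylic acid defence genes lie right of 0 (median 2.71), and the PPR, NLR and small RNA machinery medians left of 0 with TMM turned above 0 with library totals alone (0.027, 0.13 and 0.023).

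Whether the genes that gained small RNA counts were those transcribed in dxo1-2 was asked across genes. Among 4712 tested protein-coding genes with an RNA-seq level of at least 1 CPM, 2454 rose, 311 fell and 1947 did not pass, with a median log2 fold change of 1.11. The median was 1.68 with all lines as library size, 0.62 with TMM from small nuclear RNA genes (1895 higher, 734 lower) and 0.71 with a mean of at least 50 counts (462 and 137). It was 0.70 with DESeq2, which took in genes with fewer counts. The default filter can admit a gene through its dxo1-2 counts alone, and with at least 1 count in any library 3396 were higher and 338 lower among 17033 (median 0.77). Among 1818 below 1 CPM, 188 rose and 808 fell, with a median of -0.39. The median was -0.061 with at least 1 count in any library, -0.15 with DESeq2 and -0.24 with a mean of at least 50 counts. The balance narrowed to 299 higher and 376 lower with library totals alone (median -0.054) and turned to 585 and 232 with all lines (median 0.18). In 10 groups ordered by RNA-seq level the median was 1.68 in the fifth (median 9.29 CPM) and 0.50 in the highest (median 180 CPM), but the order of groups rested on the filter. With a mean of at least 50 counts the fifth group had 0.16, the eighth 2.32 and the highest 0.82, and with at least 1 count in any library the fifth had 0.84 and the highest 0.51. Across all 11534 tested genes the log2 fold change and the RNA-seq level had a Spearman rho of 0.466 and a Pearson r of 0.471, and 0.330 and 0.341 among protein-coding genes, where genes are not independent replicates. The Spearman rho was 0.291 and 0.189 with at least 1 count in any library, and 0.112 and 0.444 with a mean of at least 50 counts.

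**Figure D5:**
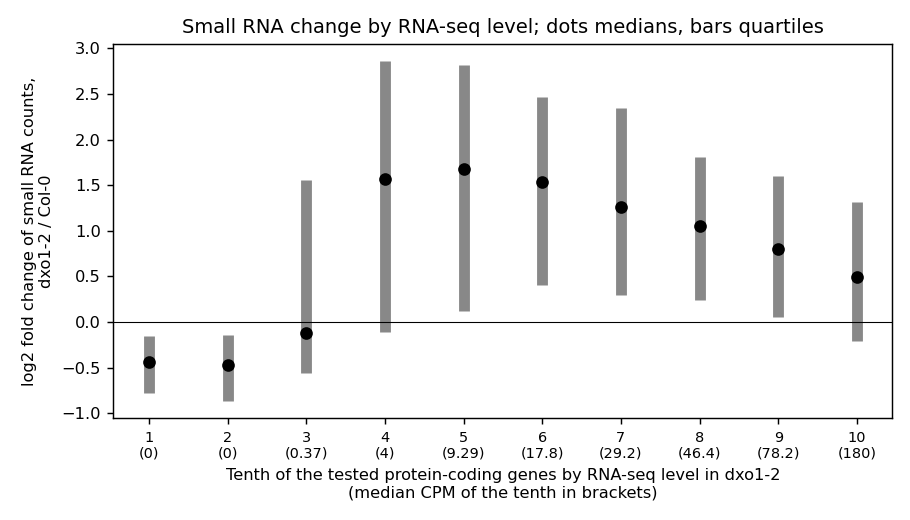
Median (dot) and quartiles (bar) of the log2 fold change of small RNA counts in 10 equal groups of 653 tested protein-coding genes, ordered by RNA-seq CPM in dxo1-2 (medians of the groups in brackets). With TMM the median is below 0 in the 3 lowest groups, which turned to 0.13, 0.11 and 0.46 with all lines as library size. It is 1.68 in the fifth group (0.16 with a mean of at least 50 counts) and 0.50 in the highest, and the highest had 0.00055 with TMM from small nuclear RNA genes.

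The dxo1-2 RNA-seq libraries were dominated by plastid transcripts, which took 48.0% ± 0.491 (SD, n = 3) of gene counts, while mitochondrial genes took 0.619% ± 0.0106. The photosystem II gene psbA stood at 146095 ± 6400 CPM and the Rubisco large subunit gene rbcL at 114619 ± 3231 CPM. They were followed by psaB (17280 ± 603), psaA (15350 ± 888), matK (11864 ± 1104) and psbB (11208 ± 682 CPM). Plastid NDH genes ranged from 860 to 4233 CPM, with ndhA highest.

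Among nuclear genes, RBCS1A had 3962 ± 415 CPM, CRD1 of chlorophyll synthesis 2118 ± 126 CPM and EF1A 1161 ± 87.4 CPM. Among the members of the gene lists, RPP7 was the highest NLR gene (187 ± 5.98 CPM), NIA2 the highest of the quality control loci (144 ± 28.8 CPM) and WRKY33 the highest defence gene (139 ± 12.0 CPM). PHO2 (76.0 ± 3.48), FRY1 (74.6 ± 6.87), AGO1 (72.5 ± 6.48), SIG6 (71.8 ± 4.87), SEN1 (20.3 ± 3.96) and the PPR locus AT1G63130 (9.21 ± 0.291 CPM) led their lists. The flower marker SEP3 (0.502 ± 0.260 CPM) and the root marker WER (0.542 ± 0.0761 CPM) were the highest of theirs. Of 27444 nuclear protein-coding genes, 17225 had a mean of at least 1 CPM. As these libraries were of 1 genotype, the levels carry no comparison with wild type.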

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

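The comparison of unaligned reads was chosen only after the result was seen. The summary line of unaligned reads, which entered the comparisons above only through all lines as library size, held 7.68% ± 0.221 (SD, n = 3) of all lines in Col-0 small RNA libraries and 8.88% ± 0.102 in dxo1-2, a difference of 1.2 percentage points with no overlap between groups. With 3 against 3 libraries an exact test cannot go below a p of 0.1.

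The 10 splits of the 6 small RNA libraries into 3 and 3 are too few for a share under 0.05. The real split called 5744 genes and was the 1 split with as many, and the highest of the other splits called 0.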

How the results depend on the processing

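TMM from pseudogenes or small nuclear RNA genes, all lines as library size, thinned dxo1-2 counts, the background of transcribed genes and levels per kb of gene span were chosen only after the data were seen, as was limiting the list medians without 1 library to members tested with all libraries. Counts of calls stayed within 1.5 times of the reported ones with RLE scaling (3131 higher, 2517 lower), DESeq2 (2532 and 2326), limma-voom (3030 and 2680), without rRNA and tRNA genes (3122 and 2679), with at least 1 count in any library (4185 and 2446) and thinned to the Col-0 depth (2876 and 2453). With each library left out in turn, 2576 to 3645 genes were higher and 1974 to 3109 lower. A mean of at least 50 counts left fewer genes to test and gave 1435 and 1286. A fold threshold of 1.5 gave 620 lower genes. Library totals alone gave 4703 higher and 809 lower, TMM from pseudogenes 1753 lower, TMM from small nuclear RNA genes 2065 and 5373, and all lines 6828 and 502. These scalings shift all genes together by construction. Of the 36 or 37 named genes tested, 32 to 37 kept their direction and their side of the threshold under each alternative, and 31 of 32 with a mean of at least 50 counts.

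The same shift moved list medians. With library totals alone the PPR loci stood at 0.027, other targets at 0.54, NLR genes at 0.13, salicylic acid genes at 3.04, small RNA machinery at 0.023, RNA decay at 0.49 and housekeeping at 0.41. With all lines these were 0.27, 0.78, 0.36, 3.27, 0.26, 0.73 and 0.64, photosynthesis genes 0.84 and chlorophyll genes 0.87, and EMB2763 had 0.21. With TMM from pseudogenes the PPR loci, other targets and small RNA machinery stood at -0.17, 0.35 and -0.17. With TMM from small nuclear RNA genes, in the order of the first listing, the medians were -0.79, -0.28, -0.69, 2.23, -0.81, -0.33 and -0.41, and photosynthesis and chlorophyll genes stood at -0.23 and -0.19.

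With 1 library left out, list medians ranged from -0.42 to -0.24 (PPR), 0.021 to 0.25 (other targets), -0.87 to -0.093 (small RNA machinery), 0.040 to 0.49 (RNA decay), -0.22 to 0.51 (housekeeping), -0.27 to -0.12 (NLR), 0.024 to 0.56 (photosynthesis) and -0.0089 to 0.67 (chlorophyll). The cause was not tested.

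With an estimated correlation the adjusted p was 0.478 for the PPR and the salicylic acid lists. Among transcribed protein-coding genes it was 0.132 for salicylic acid genes, 0.0389 for other targets and 0.000205 for NLR genes. With an estimated correlation among those genes it was 0.569, 0.457 and 0.160. Lower here, for the other targets and NLR genes, means relative to the transcribed genes, whose median log2 fold change was 1.11. The medians of the other targets and NLR genes themselves were 0.21 and -0.21. Against no change, rather than against other genes, fry gave 0.0140 for NLR genes and 0.577 for other targets. The cause was not tested.

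The replicate numbers did not pair the libraries. Correlations of the deviations of same-numbered libraries were 0.111, -0.0950 and -0.0349, and 2 of 6 libraries correlated best with their own number. With the replicate block 2913 genes were higher and 2571 lower, and camera gave adjusted p values of 0.0351 for NLR genes and 0.0106 for photosynthesis genes at the preset correlation. Without the block these lists had an adjusted p = 0.478 and 0.997 with an estimated correlation. The block changed no other list call.

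As a share of nuclear counts without rRNA and tRNA genes, the difference in percentage points was 0.144 for protein-coding genes, 1.05 for pseudogenes and -1.33 for long and other non-coding RNA genes. Without the 10 genes with most counts it was 1.87 for pseudogenes and -1.34 for long and other non-coding RNA genes. The rRNA share has no such value, since 3 of those 10 are the rRNA genes. With rRNA and tRNA genes removed by class, AT1G73650, with nearly the counts of a tRNA gene, stayed among protein-coding genes. Spearman's rho of small RNA change and RNA-seq level was 0.330 among protein-coding genes and 0.482 per kb of gene span. TMM from microRNA genes and levels per kb of exon were not run. Counts under 4 in a group limit the folds of AT1G06147, AT5G42680, PH1, GUN4 and DEG6.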

Other observations

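The tests of the fragment gain, the scaling, chromosome 4, the matched lists and the gene families were chosen only after the result was seen, the thinning for depth after the data were seen but before its own result, and the test of neighbouring genes before its result.

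Families of genes with a shared symbol stem were compared among the 2449 transcribed protein-coding genes that have a symbol. Of 33 stems with at least 8 members, 4 had a larger share of risers than the other genes in Fisher's exact test, UGT glycosyltransferase genes (16 of 19, median log2 fold change 2.93), GATA factor genes (8 of 8), HB homeobox genes (12 of 14) and CYP cytochrome P450 genes (28 of 40), each at an adjusted p of 0.0407. Against all 4712 transcribed protein-coding genes, of which 2454 rose, none of the 4 passed (0.0668, 0.0668, 0.0762 and 0.0940), so families rising together stays open. SPL genes, known for members targeted by miR156, had 0 of 9 higher and passed with a smaller share of risers against both backgrounds (adjusted p = 0.0407 and 0.0436). Genes are not independent replicates.

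Small RNA counts rose over 2454 transcribed protein-coding genes. The gain in CPM and the RNA-seq CPM had a Spearman rho of 0.125 across these genes (0.0864 to 0.164), against at least 0.989 in 100 simulations of proportional fragments. The simulations held counting error only, with no bias between the 2 library types, and the genes were chosen by their rise. The gain was thus not in strict proportion to the RNA-seq level. Whether fragments in a looser proportion caused the rise stays open. Scaling is argued against as the whole cause among the genes that the default filter kept. TMM from small nuclear RNA genes lowered all genes and still left 72.1% of the calls among transcribed genes as rises (69.5% to 78.8% with a library left out), the lowest of 7 scalings. The default filter can admit a gene through its dxo1-2 counts alone, and this scaling was not run with another count threshold. Depth is argued against too, since 89.9% of the rises were still called with dxo1-2 thinned to the Col-0 depth. Breakdown that differs between RNAs and small RNA production in dxo1-2 stay open as hypotheses, since read lengths and wild-type RNA-seq were not analysed here.

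Small RNA counts at AT1G06147, AT3G22955, DEG6 and AT2G32291 were high in 1 genotype and near 0 in the other, with no counts in the dxo1-2 RNA-seq libraries. For AT3G22955, DEG6 and AT2G32291 dxo1-2 was the genotype near 0, so their transcription in Col-0 is not known from these data. A segment linked to DXO1 is argued against, as 0 of the 4 loci lie on chromosome 4, where DXO1 lies. A deletion or insertion that reaches the neighbouring genes is argued against at 6 of the 8 neighbours, which had more than 3 counts (small RNA, with RNA-seq added in dxo1-2) in the genotype that lacks the locus. The neighbours that did not pass, of AT1G06147 and AT3G22955, had 0 counts in both genotypes and decide nothing. A change limited to the locus itself, and a difference in silencing between the lines, may each account for these values and were not tested.

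The 11 tested salicylic acid defence genes had a median log2 fold change of 2.71. The general rise of transcribed genes stays open as a cause. The median lay at the percentile 99.87 of 10000 random lists matched on RNA-seq level and small RNA count (median 1.33, middle 95% from 0.40 to 2.23). Such lists ignore the correlation among members, and camera among transcribed genes did not pass (adjusted p = 0.132, and adjusted p = 0.569 with an estimated correlation). A higher mRNA level of these genes in dxo1-2 may contribute and stays open, as wild-type RNA-seq was not analysed here.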
